A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

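Total RNA from 4 strains of Saccharomyces cerevisiae was measured, per the labels, as biotin-labelled cRNA prepared from 200 ng of RNA with the 3 prime in vitro transcription kit of the array maker. Per the labels' protocols, cells grew at 30 °C in 5 ml of YPD, a rich medium with glucose, to exponential phase at a density reading of 0.7, RNA was extracted with acid phenol and chloroform, and the deletions were made by homologous recombination with a KanMX gene. The labels gave 1 sample each of the wild type BY4742 and of strains lacking SIR2, SIR3 or SIR4, and samples were grouped by these labels.

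The deposited values were log2 levels per probe set, made by the authors with RMA per the submitters' processing notes. RMA corrects the background, normalizes the arrays to a common distribution and summarises the probes of a probe set. Its version and settings are not given in the sources used here. Because quantile normalization makes the distributions alike, a shift of all genes in 1 direction would not be seen in these values. The level of a probe set also depends on its sequence, so levels of different probe sets were not set against each other.

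The deposited values covered 10928 probe sets on 4 arrays. The annotation of the platform gave 7244 probe sets 1 symbol, 1 probe set several and 3683 none. Named probe sets were matched by gene identifier to the R64 reference table, which gave 5498 probe sets for 5449 genes of Saccharomyces cerevisiae, 5446 of them protein-coding, and 1746 probe sets for a different yeast on the same array. The probe sets without a name comprised 166 controls, 47 reporters and 3470 others. The 47 genes with several probe sets were represented by the brightest. The background level of an array was the 95th percentile of the probe sets of the other yeast, none of which differed at least 2-fold between any deletion and wild type. On all 4 arrays 94 genes lay below it. For a gene below background on 1 side, the fold change was computed with values raised to the background level and is given as at least that fold. Of the probe sets used, 128 end in a suffix for probes that match several sequences.

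Because each strain had 1 array, no test was run, no p-value is given and genes were not used as replicates. The log2 difference of each deletion from wild type was computed per gene, with a gene called at a difference of at least 1 or at most -1. Genes called in the same direction in all 3 deletions were counted. The same count was made with each other array as the reference, and on 100 simulations of unchanged arrays sharing 1 control. The spread of the simulated arrays was drawn, in 10 bins of mean level, from the deviations of the deletion arrays from their own mean. This spread includes real differences between the deletions and so can be wider than that of replicate arrays. Gene lists were described by the median difference and by its percentile among 10000 random lists of the same size matched in 10 bins of mean level. Position was described by the distance from the nearest chromosome end in the reference table, with 20 kb as the main limit.

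The lists were fixed before the data were examined, as were the 2-fold rule, the alternatives and the rule for named genes. They were the deleted genes, other silencing factors, the silent mating loci and MAT, haploid-specific, alpha-specific and a-specific genes, pheromone response, meiosis, guanine nucleotide synthesis, purine synthesis, the COS, PAU, YRF1, FLO, SNZ and SNO, THI5, MAL, AAD and HXT genes, NAD synthesis, the iron and phosphate regulons, ribosomal proteins, ribosome biogenesis, stress response, glucose-repressed genes, respiration and the marker genes of the strain background. A list of Ty elements was added after the data were seen.

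The named genes were the deleted genes and their nearest measured neighbours, the silent mating loci, IMD1 to IMD4 and GUA1, and the marker genes. To these were added the 12 genes with the largest smallest difference among those higher in all 3 deletions and likewise the 12 among those lower. For each deletion the 6 largest increases, the 6 largest decreases and the 4 genes farthest from all other arrays were named. From each list the 2 members with the largest and the 2 with the smallest mean difference were named. Genes outside this rule that are named to fill a small count or to describe a group were chosen after their values were seen.

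The alternatives were limits of 1.5-fold and 3-fold, centring each array on its median, repeating the quantile normalization over the Saccharomyces cerevisiae probe sets, leaving out genes below background on all arrays, raising values to background, leaving out probe sets that match several sequences and averaging the probe sets of a gene. Further alternatives left out each deletion in turn, required 2 of the 3 deletions, set the position limit at 10 or 30 kb, and matched random lists in 20 bins. The outermost 8 genes per chromosome end were added as an alternative after the data were seen.

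The calling rule was tested on simulated data with 5449 genes and known changes. Called in all 3 deletions were 2% of 50 genes changed by 0.7 on the log2 scale, 84% of 50 changed by 1.5, 96% of 50 changed by 2 and 100% of 50 changed by 3, and 12 of 5249 unchanged genes. Of 40 unchanged lists 1 lay outside the central 95% of random lists, and a shifted list lay at percentile 100. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.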

Results

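RNA levels were measured in 4 strains of budding yeast on Affymetrix arrays. The wild type was BY4742, a laboratory strain of mating type alpha. The other strains each lacked SIR2, SIR3 or SIR4, which together encode the Sir complex of silent chromatin. Sir2 is a histone deacetylase that uses NAD, and Sir3 and Sir4 bind nucleosomes and other silencing proteins. Each strain was represented by 1 array, so there were no replicates, no test was possible and no difference below has a replicate check. The number of arrays limits the precision of every value. The values were log2 levels per probe set, from 2.16 to 15.2, and 5449 genes of Saccharomyces cerevisiae were measured. Probe sets for a different yeast on the same arrays gave the background level, which was 4.29 in wild type, 4.32 in the SIR2 deletion, 4.39 in the SIR3 deletion and 4.28 in the SIR4 deletion. Above that level lay 5334, 5319, 5306 and 5320 genes, in the same order. Differences are log2 differences from wild type, and a gene was called higher or lower where it differed at least 2-fold.

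Each deleted gene was low in the strain labelled with its deletion and near the wild-type level in the others. SIR2 was at 9.96 in wild type and 3.68 in the SIR2 deletion, which is below background. It was at 10.34 and 9.81 in the SIR3 and SIR4 deletions. SIR3 was at 9.32 in wild type and 4.51 in the SIR3 deletion, with 9.29 and 9.44 in the SIR2 and SIR4 deletions. SIR4 was at 9.98 in wild type and 3.05 in the SIR4 deletion, also below background, with 9.78 and 9.91 in the SIR2 and SIR3 deletions. The nearest measured gene on either side of each deleted gene was not called in that deletion. PRP11 and NAT1 beside SIR2 differed by -0.21 and 0.03, RPS1A and ECM7 beside SIR3 by -0.02 and -0.41, and ADK1 and PCF11 beside SIR4 by 0.09 and -0.22. None of the 5 marker genes of the strain background was called. LYS2, which is deleted in BY4742, lay at 4.32 in wild type and differed from that by at most 0.154 in the 3 deletions, and URA3 lay below background on all 4 arrays. LEU2, also deleted in BY4742, lay above background on all 4 arrays, at 6.68 in wild type, and differed by -0.25, -0.46 and -0.57 in the SIR2, SIR3 and SIR4 deletions. HIS3 was at 11.41 in wild type and differed by 0.13, 0.13 and 0.46, and MET17 was at 12.92 and differed by -0.04, -0.22 and -0.26. None of 19 other silencing factors was called in any deletion. Their medians were -0.16, -0.06 and -0.01, with HST2 at 0.32, 0.16 and -0.04 and RIF2 at -0.83, -0.47 and -0.61. The control gene probe sets placed wild type within 0.155 of the mean of the deletions in 3 prime minus 5 prime signal for all 7 control genes.

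The design asks which genes the Sir2, Sir3 and Sir4 complex represses, so the genes higher in all 3 deletions were examined as a set. A rise in all 3 can be indirect, and these values do not tell direct from indirect changes. Per the labels the 3 deletions were also made with a KanMX gene, so an effect of that gene cannot be told apart. There were 12. HMRA1, the a1 gene of the silent mating locus HMR, was at 9.38, 9.01 and 9.80 in the SIR2, SIR3 and SIR4 deletions. Its wild-type level of 2.87 was below background, so its rise has only a bound, of at least 5.09, 4.72 and 5.51 on the log2 scale, or at least 34.4-fold on average. COS12, a member of a family of membrane protein genes found near chromosome ends, rose by 5.58, 5.37 and 5.24, from a level of 5.04, and COS8 of the same family rose by 2.67, 2.53 and 2.25. IME4, the mRNA methyltransferase of the meiotic programme, rose by 3.56, 3.66 and 3.72. IMD2 encodes inosine monophosphate dehydrogenase, which catalyses the first committed step of GTP synthesis, and it rose by 1.82, 1.96 and 1.54, or 3.42-fold on average.

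The remaining genes higher in all 3 deletions included YFR057W, YGL262W, YCR108C and YDR034C-A, which carry no standard name in the annotation. YFR057W and YGL262W were below background in wild type and at least 8.37-fold and 4.14-fold higher in the deletions on average. YCR108C rose by 3.26, 2.20 and 2.74 and YDR034C-A by 1.62, 1.66 and 1.27. DDI3 rose by 1.63, 1.37 and 1.37. The cell wall protein genes HPF1 and CWP1 were high in wild type, at 12.52 and 11.09, and rose by 1.64, 1.89 and 1.17 and by 1.74, 2.01 and 1.04. In 100 simulations of unchanged arrays that shared 1 control, a mean of 7.34 genes and at most 16 were higher in all 3 deletions, so the number 12 on its own lies within the simulated range. At a 3-fold limit 7 genes were higher, or 6 with values raised to background, against a simulated mean of 0.47 and maximum of 3, and with the SIR4 deletion set aside 27 were higher in both others.

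**Figure D1:**
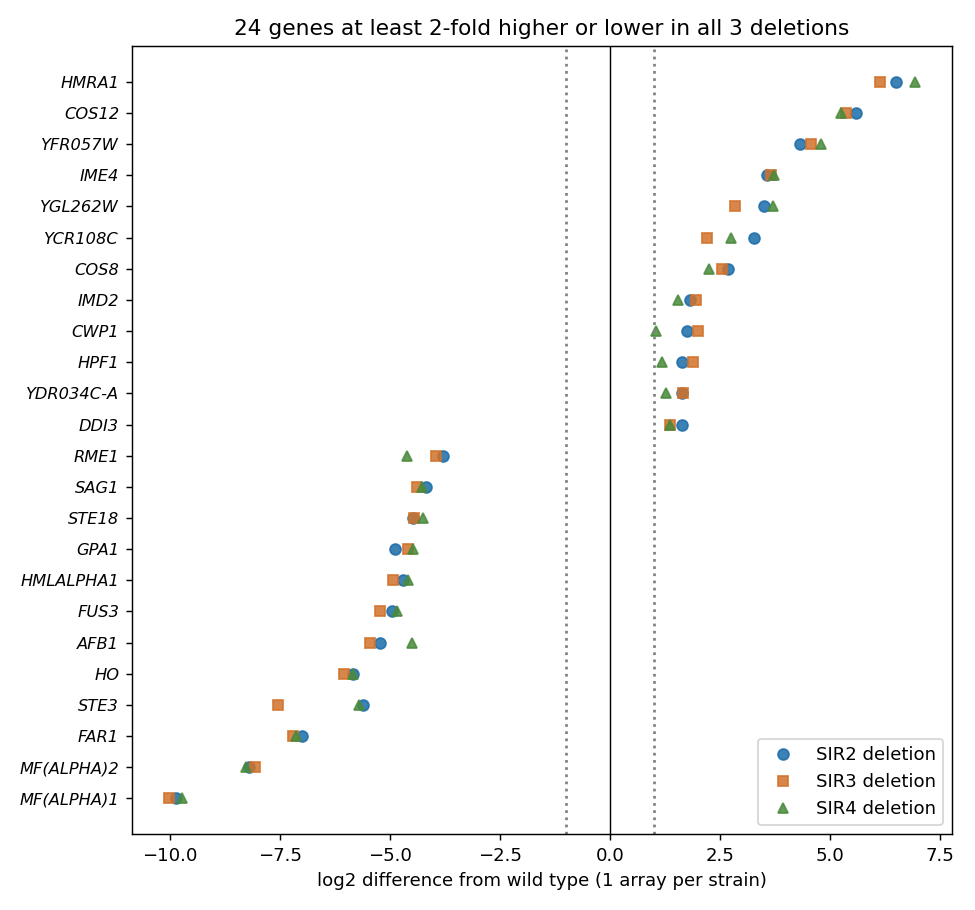
Log2 difference from wild type on the horizontal axis for 24 genes, 12 at least 2-fold higher and the 12 of 42 at least 2-fold lower with the largest smallest decrease, with a circle, square and triangle for the SIR2, SIR3 and SIR4 deletions (1 array each) and dotted lines at the 2-fold limits. The 3 symbols of a gene lie close together for most genes, with COS12 at 5.58, 5.37 and 5.24 and MF(ALPHA)2 at -8.21, -8.06 and -8.27, and genes below background on 1 side, such as HMRA1 and MF(ALPHA)1, are drawn at their measured levels, which do not fix the size of their change.

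IMD2 stood apart from the other genes of guanine nucleotide synthesis. Of 8 measured genes of this list IMD2 alone was called, and the list medians were 0.04, 0.06 and 0.08 in the SIR2, SIR3 and SIR4 deletions, the first of which was -0.03 after repeated normalization. IMD3 and IMD4, which encode the other measured isoforms of the enzyme, differed by -0.05, 0.05 and -0.09 and by 0.01, 0.10 and 0.10. GUA1, the GMP synthase gene, was at 14.00 in wild type and differed by 0.05, 0.07 and 0.06. HPT1 differed by -0.37, -0.16 and 0.14, YNK1 by 0.34, 0.09 and -0.22 and GUD1 by 0.06, 0.05 and -0.38. None of 12 genes of purine synthesis was called, with medians of -0.13, -0.04 and -0.04. ADE4 differed by -0.70, -0.41 and -0.25 and ADE16 by 0.24, 0.21 and -0.03. The IMD2 probe set is of a class that can match other sequences, and IMD1 was not measured under a probe set of its own.

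More genes were lower in all 3 deletions, and most of the largest decreases were in genes of mating and of the haploid cell type. There were 42 genes, of which 23 belonged to the lists of mating genes, where the 35 measured members of the silent mating loci, haploid-specific, alpha-specific and pheromone response lists would give 0.27 by size alone. With the 7 a-specific genes, none of which was called, the lists hold 42 measured members and the same 23 genes, against 0.324 by size. All 5 alpha-specific genes fell. MF(ALPHA)1 and MF(ALPHA)2, which encode the alpha-factor pheromone, were at 13.23 and 14.10 in wild type. MF(ALPHA)1 was below background in every deletion and at least 477-fold lower on average, and MF(ALPHA)2 differed by -8.21, -8.06 and -8.27 in the SIR2, SIR3 and SIR4 deletions. The a-factor receptor gene STE3 differed by -5.62, -7.53 and -5.69, AFB1 by -5.22, -5.46 and -4.49 and the agglutinin gene SAG1 by -4.17, -4.39 and -4.27.

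Of 12 haploid-specific genes, 11 fell in all 3 deletions, with list medians of -3.44, -3.77 and -3.87. Over the mean of the 3 deletions the median of haploid-specific genes was -3.69, and -3.63 with values raised to background. FAR1, which arrests the cell cycle in response to pheromone, was at background in each deletion and at least 100.1-fold lower on average. The endonuclease gene HO differed by -5.83, -6.03 and -5.84, and the G protein gene GPA1 by -4.88, -4.59 and -4.47. The kinase gene FUS3 and the G protein gene STE18 were below background in each deletion and at least 27.4-fold and 15.2-fold lower on average. RME1, the repressor of meiosis, differed by -3.80, -3.96 and -4.62 and RDH54 by -2.34, -2.15 and -2.18. STE12 was called in the SIR2 and SIR3 deletions at -1.34 and -1.52 and had -0.92 in the SIR4 deletion. Of 15 pheromone response genes, 8, 9 and 7 fell in the SIR2, SIR3 and SIR4 deletions and 6 in all 3, with medians of -1.01, -1.21 and -0.57. The SIR3 count is 8 with values raised to background, which ends the call of FIG1. FUS1 differed by -4.23, -5.21 and -3.73 and SST2 by -3.28, -3.47 and -2.53, while FUS2 had 0.42, -0.07 and 0.15.

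The a-specific genes showed no such falls. Their wild-type levels ran from 4.63 for AGA2 to 7.25 for STE6, against a background of 4.29, so some had little room to fall. None of 7 was called, with medians of -0.14, -0.30 and -0.05, and MFA2 differed by -0.10, -0.47 and -0.27 and BAR1 by -0.15, -0.29 and 0.16. Of the silent mating loci and MAT, 3 genes were measured. HMRA1 rose, as given above. The probe set named for HMLALPHA1, the alpha1 gene of HML, fell, by -4.70, -4.93 and -4.59 in the SIR2, SIR3 and SIR4 deletions. HMRA2 was high in wild type, at 11.15, and differed by -0.50, -0.34 and -0.29. Both probe sets are of the class shared between similar sequences, and HML and HMR carry copies of genes of the MAT locus. Among 9 meiosis genes IME4 was the only one called in all 3 deletions. IME1 had 0.91, 0.61 and 0.33, HOP1 was lower in the SIR2 deletion alone at -1.16, and SMK1 was higher in the SIR4 deletion alone at 1.01.

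The median of the haploid-specific, alpha-specific and pheromone response lists lay below all 10000 random lists of the same size and similar level in each deletion, at percentile 0. This is a description of these arrays. The number of genes lower in all 3 deletions had a mean of 8.01 and a maximum of 16 in the 100 simulations of unchanged arrays. At a 3-fold limit 31 genes were lower, or 30 with values raised to background, against a simulated maximum of 3.

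The title of the series names subtelomeric regions, and the genes were therefore grouped by distance from the nearest chromosome end. Of 77 genes within 10 kb of an end, 7 were higher in all 3 deletions, which is 9.09%. These were COS12, YFR057W and YCR108C, each the outermost protein-coding gene of its chromosome end, YGL262W next to the outermost gene, IMD2 at place 3, COS8 at place 4 and DDI3 at place 7. The probe sets of IMD2 and DDI3 are of the classes that can match several sequences, so their places are less sure. Without such probe sets 5 genes within 20 kb were higher in all 3 deletions, or 3.85%. Of 97 genes between 10 and 20 kb none was. Between 20 and 30 kb 2 of 128 genes were higher, HMRA1 and HPF1, and between 30 and 50 kb 0 of 283. Beyond 50 kb 3 of 4864 were higher, IME4, CWP1 and YDR034C-A.

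Most genes near the chromosome ends were not called higher. Of 174 genes within 20 kb, 7 or 4.02% were higher in all 3 deletions, against 5 of 5275 elsewhere, or 0.0948%. Another 155 of the 174 were called higher in no deletion, and 144 of these lay above background in wild type. The medians of the 174 genes were 0.17, 0.06 and 0.15 in the SIR2, SIR3 and SIR4 deletions, above all 10000 random lists of similar level in each. HMLALPHA1, SNO3, SOR2 and YMR317W, also within 20 kb, were lower in all 3 deletions, or 4 of 174, against 38 of 5275 elsewhere. HMLALPHA1, SNO3 and SOR2 have probe sets shared between similar sequences, so their falls cannot be placed at these ends. For HMLALPHA1 the similar sequence includes the MAT locus. Distances came from the R64 reference table and not from the deposited values, and each right end was taken as the outermost annotated feature. The outermost 8 protein-coding genes of each end, a rule that needs gene order alone, held the same number of higher genes, 7 of 180.

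**Figure D2:**
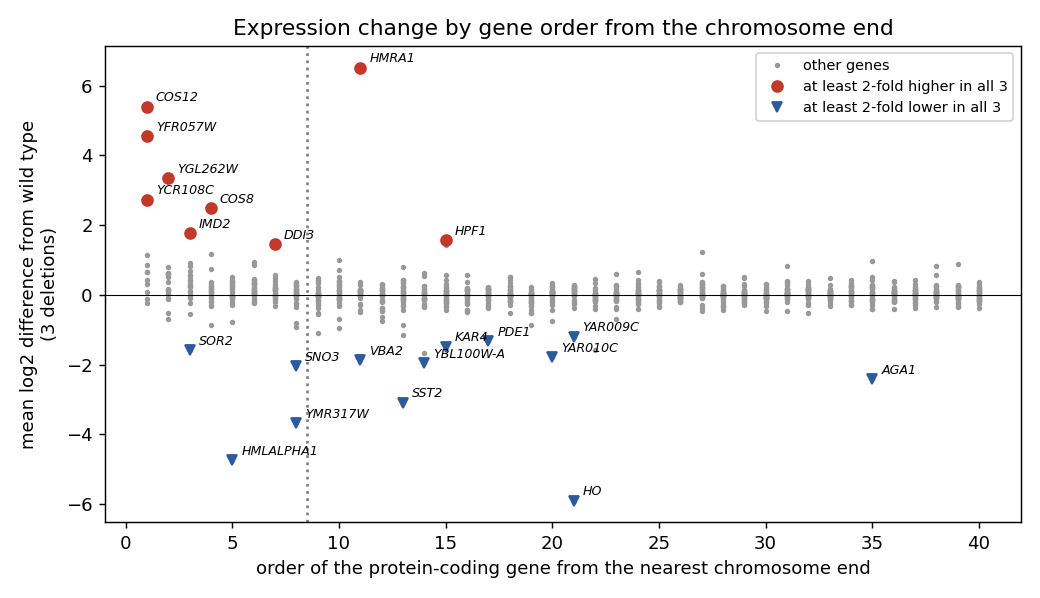
Mean log2 difference of the 3 deletions from wild type against the order of each protein-coding gene from the nearest chromosome end, for the outermost 40 genes, with red circles for genes at least 2-fold higher and blue triangles for genes at least 2-fold lower in all 3 deletions and a dotted line after place 8. Of the 9 red circles 7 lie within the outermost 8 genes, and HMRA1 and HPF1 lie at places 11 and 15.

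Several gene families with members near chromosome ends were examined, and some of their members lie elsewhere. Of 9 measured COS genes, 3, 3 and 2 were higher in the SIR2, SIR3 and SIR4 deletions, with medians of 0.77, 0.73 and 0.60 that lay at percentile 100 of random lists. COS12 and COS8 were the members called in all 3, while COS9 had 0.40, 0.12 and 0.17 and COS10 had -0.35, 0.00 and -0.04. Of 13 PAU genes, cell wall mannoprotein genes, PAU21 alone was called, in the SIR2 deletion, and it lay below background on all 4 arrays. The PAU medians were 0.07, -0.11 and 0.11, and 10 of the 13 have probe sets that match several sequences, so the values do not tell single PAU genes apart. None of 4 FLO, 5 MAL and 5 AAD genes was called in any deletion. FLO1, a flocculation gene, had -0.11, -0.30 and 0.11, MAL32 had -0.26, -0.45 and -0.91 and AAD3 had 0.01, 0.02 and 0.30. Of 4 SNZ and SNO genes, which act in vitamin B6 metabolism, 2, 3 and 2 fell, with medians of -1.39, -1.79 and -1.01. SNO1, over 50 kb from an end, had -1.98, -2.41 and -0.94, and SNO3, within 20 kb, had -1.91, -2.10 and -2.14. The thiamine gene THI13 was the measured member of its family and rose by 1.19 in the SIR2 deletion, with -0.10 and 0.43 in the others. No YRF1 gene was measured under a name of its own.

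Compared with wild type, the SIR2 deletion had the most higher genes. In it 79 genes were higher and 77 lower, and 48 of the higher genes were called in this deletion alone. COS12, IME4 and YCR108C rose by 5.58, 3.56 and 3.26, and HMRA1, YFR057W and YGL262W, below background in wild type, by at least 5.09, 2.83 and 2.20. Besides SIR2 itself, MF(ALPHA)1, MF(ALPHA)2, FAR1, HO and STE3 were among the genes that fell most. Several stress response genes rose. TSL1, a subunit of trehalose synthase, rose by 2.16 and the disaggregase gene HSP104 by 1.56, and of 20 stress response genes 6 were higher and 1, DDR2 at -1.43, lower. The list median was 0.65, at percentile 100. PNC1, the nicotinamidase gene, rose by 2.11 and BNA5 by 1.11, the members called of 11 genes of NAD synthesis, whose median was 0.37 at percentile 99.9. None of 28 ribosome biogenesis genes was called, but their median of -0.45 lay at percentile 0, with MAK16 at -0.75 and NOP4 at -0.69. RSB1 stood above every other array at 9.83, with 8.33 in wild type, and PRM7, YNL034W and SIR2 below every other array, PRM7 with -1.76. On the chromosome PRM7 is the next protein-coding gene beyond NAT1, the neighbour of SIR2. Whether its fall came from the change made at the SIR2 locus was not tested.

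In the SIR3 deletion 40 genes were higher and 91 lower, and 22 of the lower genes were called in this deletion alone. HAP4, the activator of respiratory genes, rose by 2.27 and was at 0.61 in the SIR2 deletion and 0.61 in the SIR4 deletion. Of 12 respiration genes 3 were higher, among them the succinate dehydrogenase gene SDH1 at 1.40 and the citrate synthase gene CIT1 at 1.11. The respiration medians were 0.53, 0.70 and 0.28 in the SIR2, SIR3 and SIR4 deletions, at percentile 100 in each. Of 15 iron regulon genes 5 were lower and 10 were not called, with FIT2 and FIT3, which encode cell wall proteins that retain iron, at -2.93 and -1.97. The list medians were -0.21, -0.73 and -0.40, at percentiles 1.52, 0 and 0, while FRE1 had 0.13, 0.03 and 0.19. Of the stress genes 1 was higher, HSP104 at 1.20, and 3 lower, with DDR2 at -2.19 and HSP26 at -2.06, and the median was 0.07. The ribosome biogenesis median was -0.16 at percentile 0. CIS1 fell by 2.93 on the log2 scale and was the gene farthest below every other array after SIR3 and STE3.

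The SIR4 deletion had the fewest genes called, 19 higher and 60 lower, with 3 higher and 5 lower in this deletion alone. COS12, IME4 and YCR108C rose by 5.24, 3.72 and 2.74, and HMRA1, YFR057W and YGL262W by at least 5.51, 3.30 and 2.41. HXK1, which encodes a hexokinase, fell by 1.28 on the log2 scale, where it rose by 1.17 in the SIR2 deletion and had 0.62 in the SIR3 deletion. The aldehyde dehydrogenase gene ALD6 had -1.04, with 0.51 and 0.21 in the SIR2 and SIR3 deletions. FIT2 and FIT3 were lower at -1.70 and -1.31. Of the stress genes none was higher and 2 were lower, HXK1 and HSP26 at -1.33, with a median of -0.18 at percentile 0.03. PNC1 had 0.04, and the NAD synthesis median was 0.21 at percentile 99.9, against 0.16 at percentile 98.5 in the SIR3 deletion. The ribosome biogenesis median was 0.04 at percentile 70.6. No respiration gene was called in this deletion.

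Other lists showed few calls. Of 14 HXT genes, hexose transporters, 5 were not above background on any array, and HXT5 was the 1 called, lower in the SIR2 and SIR3 deletions at -1.46 and -1.34. The HXT medians were 0.21, 0.12 and -0.03. Of 11 phosphate regulon genes PHO89 was lower in the SIR2 deletion at -1.51 and PHM8 in the SIR4 deletion at -1.25, with medians of -0.07, -0.04 and 0.02. Of 10 glucose-repressed genes 1 was called, CIT2 at 1.04 in the SIR2 deletion, with medians of 0.21, -0.06 and 0.08 and ADH2 at 0.41, 0.37 and 0.52. None of 122 ribosomal protein genes was called, and their medians were 0.00, 0.01 and 0.00.

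**Figure D3:**
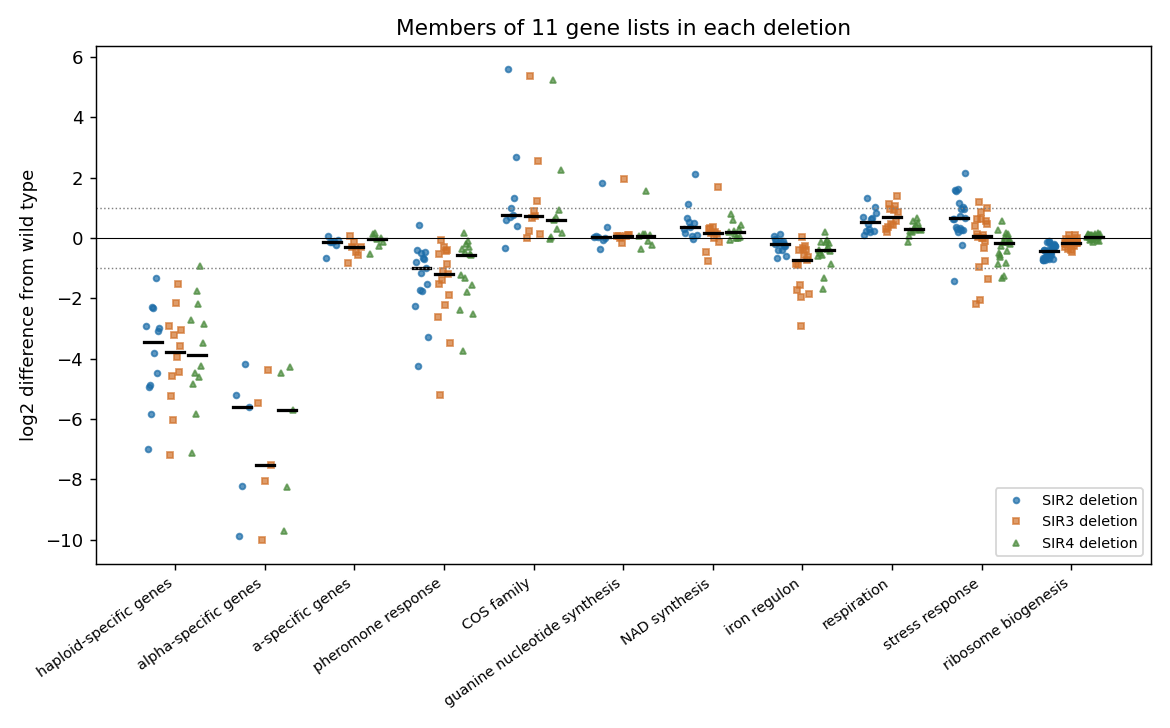
Log2 difference from wild type of each measured member of 11 gene lists, with a circle, square and triangle for the SIR2, SIR3 and SIR4 deletions (1 array each), black bars at the list medians and dotted lines at the 2-fold limits. The haploid-specific medians lie at -3.44, -3.77 and -3.87 and the stress response medians at 0.65, 0.07 and -0.18.

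The 3 deletions were then compared with each other. Genes called in the SIR2 and SIR3 deletions but not in the SIR4 deletion numbered 15 higher and 15 lower. Among the higher ones were PNC1, HSP104, CIT1 and SDH1. For SIR2 and SIR4 the numbers were 4 higher and 1 lower, and for SIR3 and SIR4 0 higher and 12 lower. Directly between arrays, 57 genes differed at least 2-fold between the SIR2 and SIR3 deletions, 90 between SIR2 and SIR4 and 69 between SIR3 and SIR4. Wild type differed at 156, 131 and 79 genes from the SIR2, SIR3 and SIR4 deletions. The SIR2 and SIR3 deletions each had 15 genes at least 2-fold apart from all other arrays in 1 direction, and the SIR4 deletion had 3, SIR4, HXK1 and ALD6.

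The differences from wild type correlated across genes between deletions, with r = 0.812 for SIR2 and SIR3, 0.707 for SIR2 and SIR4 and 0.773 for SIR3 and SIR4, where genes are not independent replicates. Unchanged arrays sharing 1 control gave a mean r of 0.499 in simulation, since all 3 differences contain the same wild-type array. The mean covariance was 0.180 against 0.0508 simulated, a difference of 0.130. Without the 35 mating genes and the deleted genes, but with the a-specific genes, the mean r over 5411 genes was 0.617 and the mean covariance 0.0769. The SIR2 and SIR3 deletions shared 27 higher and 57 lower genes, against at most 21 and 20 in the simulations of unchanged arrays sharing 1 control. SIR2 and SIR4 shared 16 higher and 43 lower genes, against at most 21 and 18, and SIR3 and SIR4 shared 12 and 54, against at most 20 and 21. The SIR4 deletion had 19 higher genes in all, so its shared higher genes could not exceed these simulated maxima. For them the comparison decides nothing. Independent lists of these sizes, which leave out the shared array, would share 0.58 and 1.29, 0.275 and 0.848, and 0.139 and 1.002 genes in the same order. Part of the overlap may come from the shared wild-type array, which cannot be split. With the SIR2, SIR3 or SIR4 deletion array as the reference in place of wild type, 6, 10 and 3 genes were higher and 9, 5 and 0 lower on all 3 other arrays, against 12 and 42 with wild type.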

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

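All tests in this part were chosen only after the results they measure were seen. The following values stood out because a gene moved in opposite directions in different deletions or because probe sets outside the gene comparisons differed from wild type.

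HXK1 was called higher in the SIR2 deletion and lower in the SIR4 deletion, a distance of 2.44 on the log2 scale, and this difference between deletions was not tested, since each strain had 1 array.

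Among 3517 unnamed and reporter probe sets, 5 were higher in all 3 deletions and none lower. The smallest of the 3 differences was 1.31 for the unnamed probe set 1773061_s_at, 1.40 for 1776828_at and 1.84 for 1778878_s_at. For 1777712_at, which was below background in wild type, it was at least 2.26. The reporter probe set RPTR-Sc-AJ002682-1_s_at was at 2.96 in wild type and at 14.6 in each deletion, a difference of at least 10.3 on the log2 scale. The labels state that the deletions were made with a KanMX gene, and the probe set carries no gene name in the annotation used here.

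Another 6 reporter probe sets were at background in the SIR4 deletion alone. With values raised to background, the differences from wild type were -3.20 for RPTR-Sc-J01347-1_at, -4.26 for RPTR-Sc-J01347-1_s_at, -8.20 for RPTR-Sc-J01347-2_at, -7.88 for RPTR-Sc-J01347-3_at, -8.75 for RPTR-Sc-J01347-4_at and -5.66 for RPTR-Sc-U46493-1_s_at, each a bound on the loss. In the SIR2 and SIR3 deletions none of the 6 differed by 2-fold.

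A defect or the scaling of the SIR4 array is argued against, because outside these 6 probe sets only 1 lay at least 4 on the log2 scale below every other array, and that was the probe set of SIR4 itself. The highest of the 6 levels on this array was 3.53, under its background level of 4.28, which is consistent with a sequence missing from this strain. Whether such a loss would be tied to the deletion of SIR4 or to the history of 1 culture was not tested. The gene counts of this deletion do not use these probe sets.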

How the results depend on the processing

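The outermost 8 genes per chromosome end were chosen only after the data were seen, and the other alternatives were planned. No paired analysis was possible because each strain had 1 array and no test was run. Each named gene was checked by its mean difference over the 3 deletions, a deleted gene by its own deletion, and each list by the mean of its 3 medians. None of these values that was at least 1 in size changed sign under any alternative run. Calls in single deletions could: YBR072C-A and YBR298C-A, at -1.27 and -1.30 in the SIR3 deletion, had 0.10 and 0.08 with values raised to background. For named genes and lists 940 values stayed within their margin and 8 did not, while for counts and summaries 90 did and 27 did not. Many of the 940 could not move. Leaving out probe sets does not change the difference of a kept gene with 1 probe set, and averaging changes only the 47 genes with several. The fold limit moved the most. At 1.5-fold, 295 genes were higher and 276 lower in the SIR2 deletion, 148 and 206 in SIR3, 77 and 114 in SIR4, and 34 and 76 in all 3. At that limit 16 genes within 20 kb of an end were higher in all 3, or 9.20%, and 18 elsewhere. At 3-fold, 28 were higher and 43 lower in SIR2, 15 and 50 in SIR3, 8 and 37 in SIR4, and 7 higher in all 3, of which 2 lay beyond 20 kb. A higher limit passes fewer genes by construction. With the SIR4 deletion set aside 27 genes were higher in both others, and in at least 2 of the 3 deletions 31 were higher and 70 lower, since fewer deletions are then required. With a limit of 10 kb the share near the ends was 9.09%, and with 30 kb 3 higher genes lay beyond it. The mean correlation between comparisons was 0.524, 0.331 and 0.311 with the SIR2, SIR3 and SIR4 deletion as the reference. The cause was not tested. Raising values to background moved 7 of 133 named genes, HMRA1, MF(ALPHA)1, PAU21, SIR2, SIR4, YFR057W and YGL262W, whose size signal over background then limits. It ended 3 higher and 2 lower calls in the SIR2 deletion, 1 and 8 in SIR3 and 0 and 4 in SIR4, among them PAU21 in SIR2, FIG1 and YAR066W in SIR3 and LSO1 in all 3, which leaves 41 genes lower in all 3. Without probe sets that match several sequences, the silent mating loci list held HMRA1 alone, whose rise has only a bound. Matching random lists in 20 bins moved 2 of 84 percentiles across the central 95% limit. Rescaling the arrays changed the sign, after rounding to 3 decimals, of 7 of 84 list medians, each at most 0.105 in size as deposited. For the marker genes in the SIR4 deletion the median only rounded to no difference, from -0.0016 to -0.0001 with centring, and stayed negative.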

Other observations

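The tests of the explanations below and the list of Ty elements were chosen only after the results they measure were seen, while the medians and percentiles of the stress, ribosome biogenesis and glucose-repressed lists and the repeated normalization were planned.

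Several Ty elements, the retrotransposons of budding yeast, were lower in the deletions. Of 11 measured members, 6, 7 and 7 were called lower in the SIR2, SIR3 and SIR4 deletions and 5 in all 3, with medians of -1.01, -1.13 and -1.36. YGR109W-A, part of a Ty3 element, differed by -3.43, -3.79 and -3.16, and YAR010C by -1.67, -2.10 and -1.59. Transcription of Ty1 and Ty3 is known to be lower in diploid cells of type a/alpha than in haploids. Of these members 10 have probe sets that match several sequences, so the values do not tell single elements apart.

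Besides the mating lists, 19 genes were lower in all 3 deletions, of which 5 were the Ty elements described above. Among them ICS2 had a mean difference of -3.57, YMR317W of -3.68, MHF2 of -2.31, the transcription factor gene TEC1 of -1.75, STE14, which encodes a methyltransferase that acts on a-factor, of -1.75, and AMN1, a gene of daughter cell separation, of -1.30. Genes higher in the SIR2 and SIR3 deletions but not in the SIR4 deletion included GPD1, the glycerol pathway gene, at 1.86 in SIR2 with 0.61 in SIR4, and CAR2 of arginine breakdown at 1.95 in SIR2 with 0.49 in SIR4.

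The genes lower in all 3 deletions may reflect mating-type information of both types being expressed in the deletion strains, as a hypothesis, since HMRA1 rose and 11 of 12 haploid-specific genes fell in all 3. The haploid-specific genes are part of the pattern itself, so they are no separate test. Neither mating programme rose, as all 5 alpha-specific genes fell and none of 7 a-specific genes was called. The hypothesis concerns mating-type information and not these programmes, so this does not argue against it. Lower RNA quality of the wild-type array is argued against by the 3 prime minus 5 prime signal, in which wild type lay at most 0.155 from the mean of the deletions. Wild type did lie above that mean for every control gene but TDH1, though by small amounts. A background with an intact LYS2 is argued against by the LYS2 level, which differed by at most 0.154. Chance spread of the wild-type array is argued against for the mating lists, which held 23 of the 42 genes where their size gives 0.27. For the 19 genes outside these lists it stays open, since no second wild-type array measured that spread. Simulated unchanged arrays gave at most 16 such genes. The 19 include 5 Ty elements. Their shared probe sets do not tell single elements apart, so the 19 may not all be separate genes. At 3-fold the count was 10, or 9 with values raised to background. The simulated maximum was then 3, and a deletion array as the reference gave at most 1.

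Stress response genes had medians of 0.65, 0.07 and -0.18 in the SIR2, SIR3 and SIR4 deletions. The SIR2 minus SIR4 median was 0.83 as deposited and 0.86 after repeated normalization. The deposited values were already normalized to a common distribution, so the repeat could change little. It therefore does not decide whether scaling of the arrays had a part. A shared stress or growth-rate programme is a candidate explanation, because the ribosome biogenesis median was -0.45 in the SIR2 deletion, at percentile 0 of random lists. Density or glucose of the single cultures cannot be told apart from an effect of the deletions, since there was 1 culture per strain and the glucose-repressed median of 0.21 in the SIR2 deletion lay at percentile 95.8.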
